A study of Homo sapiens with 9 samples.

How the data were processed

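Total RNA from 3 samples each of parental IGROV-1, IGROV-1/Pt1 and IGROV-1/OHP cells had been hybridized to Illumina bead arrays, 9 arrays in all. The submitters describe the samples as independent biological replicates. The values deposited by the authors are intensity values for 48803 probes on a linear scale. BeadStudio is named in the labels without a version. From the values, they were quantile normalized between arrays, since the sorted columns differed by at most 1.08%, and not background subtracted, with a lowest value of 125.13 and a highest of 71072.36 on every array. A second deposited table holds 9 signal columns with detection p-values under array names that no label pairs with a sample. These 9 columns were not matched to samples and are not used here. A fallback for a file without detection p-values had been set before the data were examined. As the detection p-values here could not be matched to samples, an adapted form of that fallback was used. For all comparisons, lists and named genes, normexp background correction in limma with offset 50 was applied to the deposited, already normalized values. It was followed by log2, without a further quantile step and with no detection filter. The sample labels, which call OHP oxaliplatin-resistant, were followed, although the description of the series names cisplatin for both resistant lines.

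Gene symbols were taken for 28098 probes with 1 symbol, while 13 probes with several and 20692 without a symbol were left out. Of 18852 genes, 6132 had more than 1 probe, and the probe with the highest mean log2 value represented the gene. The genes with probes past the test in both directions numbered 3 in Pt1 against parental, 1 in OHP against parental and 1 in OHP against Pt1, and none of these is named. The 97.5 percentile of 431 olfactory receptor probes, genes not expected in these cells, gave a background ceiling of 302.19 intensity units, chosen after the data were examined. Above it in all arrays of a line were 10700 genes. A gene at or under the ceiling on all 3 arrays of 1 line is given as a bound on its fold, the geometric mean of the other line's deposited intensities over the ceiling. Of the genes, 18828 were found in the reference gene table, whose assembly, GRCh38.p14, served only to find which genes neighbour each other.

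limma 3.58.1 in R 4.3.3 fitted all 9 arrays in 1 model (lmFit and eBayes, 6 residual and 3.47 prior degrees of freedom), with contrasts of Pt1 against parental, OHP against parental and OHP against Pt1, and a moderated F-test over the 3 lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 18852 genes within a contrast, 2-sided, and counts at least 2-fold (log2 fold change of 1) stand beside. Errors are SE from the fit. In 30 gene lists of 749 genes, fixed before the data were examined, 699 genes were measured. Each list was tested with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 30 lists, and fry was run beside it. Of 5, 5 and 1 lists called in the 3 contrasts with the preset correlation, 0 held with an estimated correlation. A list is called here by camera alone. In fry the interferon list passed in the 3 contrasts, at adjusted p = 0.000547, 0.0103 and 0.002955. NF-kB targets passed it in Pt1 and OHP against parental, at 0.000745 and 0.00169. Of the other called lists, cholesterol in both lines, proliferation in Pt1 and antigen presentation in OHP did not pass fry. Other lists that camera did not call passed, among them platinum transporters as lower, at 0.000648, 6.5e-05 and 0.00119. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

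Named genes followed a rule. For each resistant line against parental these were the 12 largest rises and 12 largest falls among called genes above background on all 3 arrays of the higher line and without overlap between the lines. For OHP against Pt1 they were the 6 largest each way, for changes in both lines the 8 largest each way, and for each list up to 4 called members with the largest change. A set of genes of platinum response and ovarian cancer was to be named whatever the result, of which some are not analysed here. The background ceiling stands in for the detection p-value in that rule.

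On data simulated for Pt1 against parental (18852 genes, 50 changed at each size), the fit recovered 4%, 36%, 84% and 98% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 5 false calls and 0 of the wrong sign. With 30 lists of which 1 was shifted, the shifted list had adjusted p = 4.41e-65 and 0 unchanged lists were called. Genes were simulated independently of each other and with the same spread on every array. These simulated lists therefore cannot show false calls from correlation between genes, which was estimated at 0.268 for the cholesterol list. Pairing of same-numbered arrays was checked by the correlation across genes of deviations from the group means, 0.182, 0.045 and -0.004 for Pt1 and parental, 0.126, 0.671 and 0.502 for OHP and parental, and 0.021, -0.011 and -0.192 for OHP and Pt1. All 3 pairs of OHP and parental arrays exceeded 0.1. Deviations from the mean of 3 arrays depend on each other. A shift shared by OHP array 2 and parental array 2 alone could therefore raise all 3 correlations. The labels state no shared day or batch, so pairing is not established. As a precaution, results that changed with replicate number as a block are given with their blocked value.

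The signal shift index of an array is the mean log2 value of the 200 probes most dimmed on OHP array 2 against the other OHP arrays minus that of the 200 most brightened, chosen on OHP arrays alone among probes with a mean intensity of at least 1000. The probe-pair index is the mean log2 difference within 200 of 1305 pairs of bright probes of 1 gene, turned the way it moved on OHP array 2. Runs of neighbouring genes were sought along 10690 ordered genes above background with medians over windows of 25 genes, against the extremes of 100 shuffles of the order. To check the search, 50 neighbouring genes were shifted by -1 on the log2 scale in the OHP against parental values in shuffled order. Of these 100% were found, and 0 runs were found without the shift. The order without the shift was a shuffle like those that set the extremes, so its 0 runs say little about false runs. Alternatives to the processing were no background correction, offset 16, filters at the background ceiling, every probe by itself, a variance trend with robust estimation, array weights, the replicate block, only the 6 arrays compared, a test against a log2 fold change of 0.5, leaving out arrays, and the signal shift index as a covariate.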

Results

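The data were gene expression profiles of 3 human ovarian carcinoma cell lines of one origin, measured on Illumina bead arrays hybridized with biotinylated cRNA. Parental IGROV-1 cells are sensitive to cisplatin, a platinum drug that crosslinks DNA. IGROV-1/Pt1 (Pt1) is its cisplatin-resistant variant, and IGROV-1/OHP (OHP) is labelled as the variant resistant to oxaliplatin, a related platinum drug with a different carrier ligand. The description of the series instead names cisplatin as the drug that gave rise to both resistant lines, so the drug behind the OHP comparisons is uncertain. Each line was represented by 3 arrays, from samples described as independent, which makes 9 arrays. The deposited intensities had a median between 228.2 and 228.34 on every array, and between 10300 and 10516 of 18852 genes lay above the background ceiling of 302.19 intensity units. The small number of arrays limits the precision of every value. Fold changes are given on the log2 scale with their SE from the limma fit (n = 3 arrays in each line). A gene at background on all 3 arrays of its dimmer line has only a bound, given as at least so many fold from the deposited intensities. A gene at background on some of these arrays is given by its fitted value, which then rests partly on background. Among such genes are TNFRSF14, C8G, CA12, ENO2 and SGCE, which in OHP lay above the ceiling on array 2 alone. For every gene that was named by the size of its change, the 3 arrays of the higher line all lay above the 3 of the lower line. This was a condition for naming the largest rises and falls, so it adds no support to them. Over all 18852 genes it held for 39.43% in Pt1 against parental, 18.59% in OHP against parental and 27.77% in OHP against Pt1.

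Replicates of a line resembled each other closely except on OHP array 2. Across genes, which are not independent replicates, the Pearson correlation was 0.987 to 0.99 between parental arrays, 0.993 to 0.994 between Pt1 arrays and 0.99 between OHP arrays 1 and 3. OHP array 2 correlated with the other OHP arrays at 0.942 and 0.926, less than with parental array 2, at 0.956. OHP arrays 1 and 3 correlated with parental array 2 to a like degree, at 0.962 and 0.952. An index of signal shift, built from 200 bright probes on each side that parted OHP array 2 from the other OHP arrays, was -4.22 there against 1.35 and 2.30 on OHP arrays 1 and 3. Parental array 2 stood at -1.55 on the same index, while the other parental arrays were at 0.13 and 0.65 and the Pt1 arrays between 1.49 and 1.82.

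**Figure D1:**
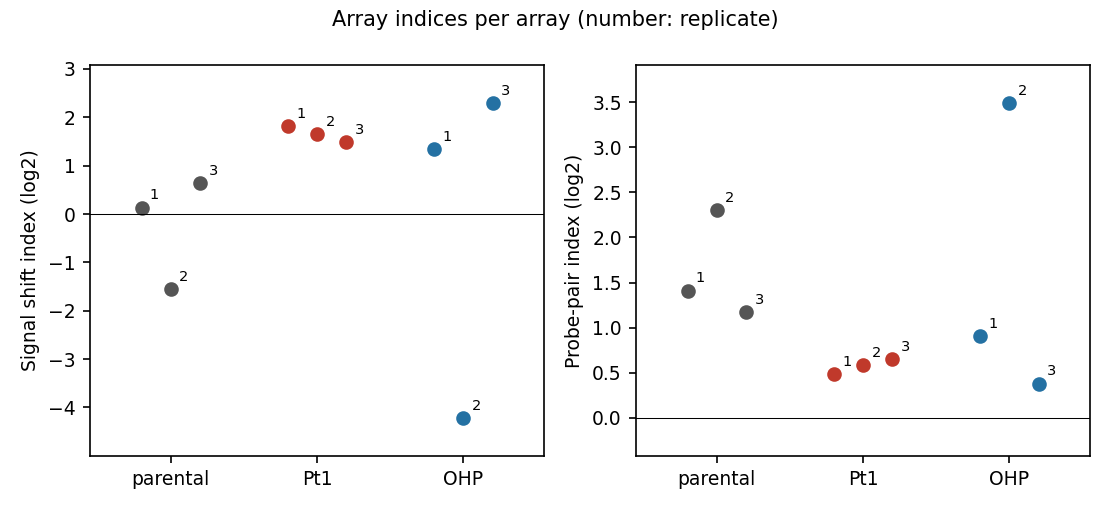
Signal shift index (left) and probe-pair index (right), both on the log2 scale, for each of the 9 arrays by line, 1 labelled point per array. OHP array 2 lies apart at -4.22 and 3.49, and parental array 2 is nearest to it at -1.55 and 2.30.

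The comparison of Pt1 with parental cells asked which genes differ between cisplatin-resistant and sensitive cells. Of 37 interferon-stimulated genes 24 were higher in Pt1, as were the chemokines CCL2 and CXCL8, together with the receptor tyrosine kinase AXL and the surface antigen MSLN. The adhesion molecule EPCAM, the cytoskeletal gene TPM2, several drug transporters and the cell cycle inhibitor CDKN1A were lower. Of 18852 genes, 1863 (9.88%) differed between the lines, 783 higher and 1080 lower in Pt1. A change of at least 2-fold was seen for 505 of the higher and 726 of the lower genes. The spread is pooled over all 9 arrays, and the count was 4877 without OHP array 2, 1124, 1039 and 1104 without Pt1 arrays 1, 2 and 3, and 1217 and 1141 without parental arrays 1 and 2.

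FAM107A, CCL2 and MSLN were among the genes that rose furthest in Pt1. FAM107A, an actin-binding protein of the stress response, was at least 65-fold higher. CCL2, which draws monocytes, was at least 37-fold higher, and CXCL8, which draws neutrophils, rose by 5.43 ± 0.42. MSLN, mesothelin, a surface glycoprotein of mesothelial and ovarian carcinoma cells, rose by 5.81 ± 0.28. The lipid raft protein MAL, which sorts cargo to the apical membrane, rose by 6.25 ± 0.20. AXL, a receptor tyrosine kinase activated by GAS6, was at least 22.4-fold higher. QPRT, an enzyme of NAD synthesis, was at least 25.9-fold higher, and PTGR1, a reductase that inactivates lipid aldehydes, was at least 15.4-fold higher. MCUB, an inhibitory subunit of the mitochondrial calcium channel, was at least 24.1-fold higher, and the centrosomal protein TACC1 was at least 21.1-fold higher. The cancer-testis antigens CT45A3 and SSX1, normally restricted to germ cells, rose by 5.64 ± 0.19 and 5.56 ± 0.31. Adjusted p over these 12 genes ran from 1.50e-07 to 4.02e-05.

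HBA2, TPM2 and EPCAM were among the genes that fell furthest in Pt1. HBA2, an alpha globin, was at least 179-fold lower, and PAGE1, a cancer-testis gene, was at least 91.1-fold lower. TPM2, a tropomyosin of actin filaments, was at least 65.5-fold lower. EPCAM, an epithelial adhesion molecule, was at least 67-fold lower. RADX, which binds single-stranded DNA at replication forks, was at least 40.6-fold lower. The keratin KRT24 fell by 7.06 ± 0.27, and ANKRD22, an ankyrin repeat protein, was at least 38-fold lower. TNFRSF14, a receptor that signals to lymphocytes, was at least 50-fold lower. HLA-DMB, which loads peptides onto class II molecules, was at least 41.5-fold lower. LBP, which binds bacterial lipopolysaccharide, fell by 6.36 ± 0.26, the secreted protease KLK11 fell by 6.12 ± 0.30, and the kinase anchor AKAP19 was at least 26.4-fold lower. Adjusted p over these 12 genes ran from 4.04e-08 to 9.36e-06.

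Among interferon-stimulated genes, 24 of 37 measured rose in Pt1, none fell and 13 did not pass, and 27 changed adjusted over the list alone. Their median log2 fold change was 1.49, or 1.36 over the 34 members above background in either line with bounded genes at their bound. The list stood out from the other genes in camera (adjusted p = 5.66e-19 with the preset correlation, adjusted p = 0.0899 with an estimated correlation). IFI27 rose by 5.0 ± 0.36 and IFI44 rose by 4.13 ± 0.37. OAS1, which makes the activator of an antiviral RNase, was at least 4.47-fold higher, and IFIT2, which blocks translation of viral RNA, rose by 3.12 ± 0.28. Of 31 NF-kB targets and cytokines, 8 rose, 1 fell and 22 did not pass, with 11 changed adjusted over the list alone, a median of 0.39 (0.70 with bounds over 22 members) and adjusted p = 3.72e-05 with the preset correlation (adjusted p = 0.137 with an estimated correlation). CXCL10, a T cell chemokine induced by interferon, was at least 5.29-fold higher, and the cytokine IL32 rose by 3.09 ± 0.22. The member that fell was LIF, at -1.44 ± 0.37 (adjusted p = 0.0371) on the log2 scale, named after its value was seen. In antigen presentation, 4 of 21 genes rose and 2 fell, with 7 changed adjusted over the list alone: the immunoproteasome gene PSMB9 rose by 3.03 ± 0.62 and TAPBP, of the peptide loading complex, rose by 0.78 ± 0.14, whereas the class II gene HLA-DMA fell by 1.47 ± 0.28. With 1 array left out, the test was no longer passed by PSMB9 (without any 1 of the Pt1 arrays or parental array 1 or 2, adjusted p up to 0.0597).

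**Figure D2:**
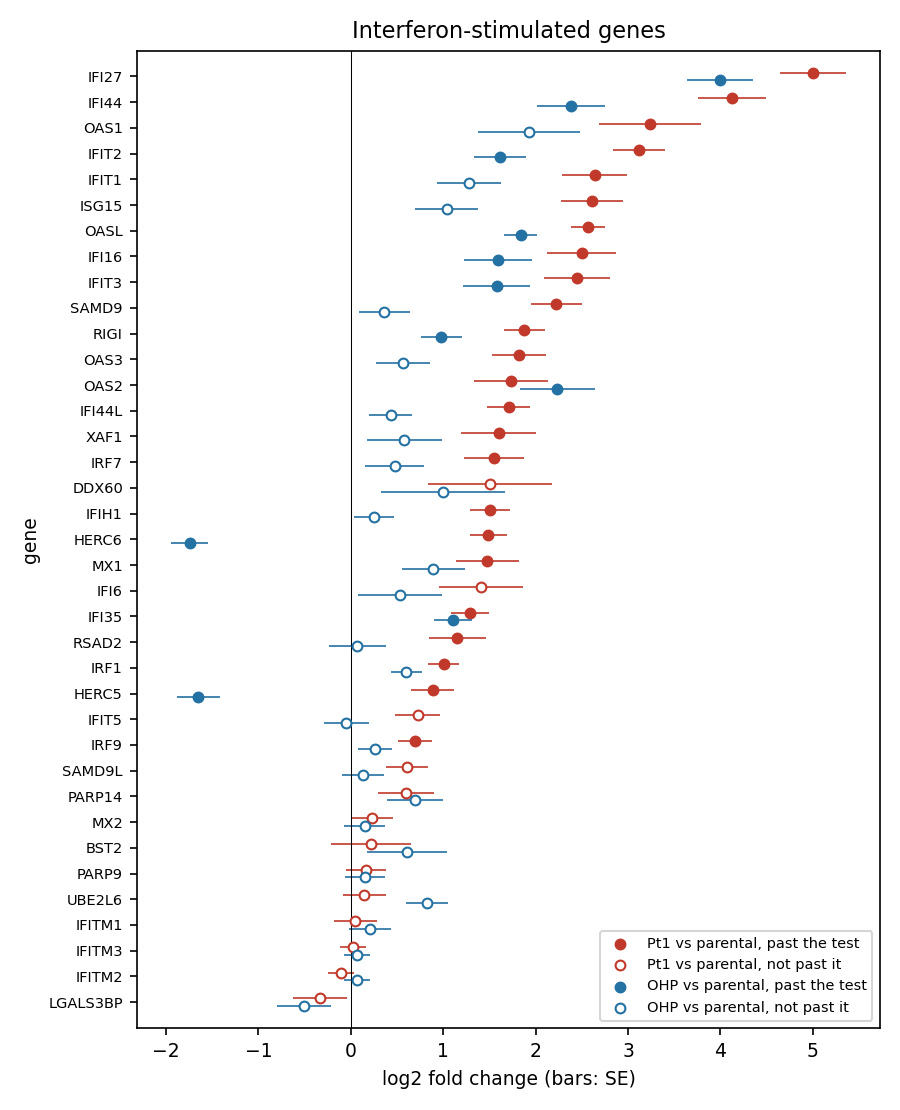
Log2 fold change against parental cells of the 37 measured interferon-stimulated genes in Pt1 (red) and OHP (blue), with bars of 1 SE from the fit on 3 arrays per line; filled points are past the test. In Pt1 24 genes were higher and 0 lower, and in OHP 9 were higher and 2 lower.

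Platinum transporters moved both ways in Pt1, with 1 of 19 higher, 5 lower and 6 changed adjusted over the list alone. ABCC2, a pump that exports glutathione conjugates, was at least 5.98-fold higher (adjusted p = 0.000107). The related pump ABCC3 fell by 2.91 ± 0.33 (adjusted p = 0.000421), and the multidrug pump ABCB1 fell by 2.60 ± 0.25 (adjusted p = 0.000163). ATP7B, a copper ATPase, fell by 2.10 ± 0.23 (adjusted p = 0.000323). The copper importer SLC31A1 and the copper ATPase ATP7A did not pass the test, at 0.46 ± 0.65 (adjusted p = 0.765) and 0.02 ± 0.21 (adjusted p = 0.979). With the signal shift index as a covariate and without OHP array 2, SLC31A1 turned to -0.89 and passed (adjusted p = 0.0400). Of 9 metallothioneins, 2 rose, MT2A by 1.68 ± 0.25 and MT1X by 1.38 ± 0.34, with 3 changed adjusted over the list alone. Only 3 of the 9 lay above background in either line. The list was not called (adjusted p = 0.207 with the preset correlation). With only genes above the ceiling in all 9 arrays it was, at adjusted p = 0.0276. In the glutathione and NRF2 list, 2 of 38 genes rose and 2 fell, with 5 changed adjusted over the list alone. The reductase AKR1C3 rose by 2.89 ± 0.20, the synthetase GSS rose by 0.77 ± 0.16, and the peroxidase GPX1 fell by 1.31 ± 0.33. GSTP1, a glutathione transferase, did not pass at -0.18 ± 0.13 (adjusted p = 0.496). The call ended, with 1 array left out, for MT1X (without any 1 of the Pt1 arrays or any 1 of the parental arrays, adjusted p up to 0.120), GSS (without Pt1 array 1 or 3 or parental array 1 or 2, adjusted p up to 0.0717) and GPX1 (without any 1 of the Pt1 arrays or any 1 of the parental arrays, adjusted p up to 0.124).

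Few DNA repair genes changed in Pt1. ERCC1, part of a nuclease of nucleotide excision repair, fell by 1.02 ± 0.21 (adjusted p = 0.0132), and GTF2H4 of the same pathway fell by 0.80 ± 0.18, the 2 genes of 27 that changed, also adjusted over the list alone. In homologous recombination and the Fanconi anaemia pathway, EME1 rose by 0.89 ± 0.24, alone among 33 genes, with 0 changed adjusted over the list alone, and BRCA1 did not pass at 0.54 ± 0.18 (adjusted p = 0.103). SHPRH fell by 1.04 ± 0.14 as the only change among 15 genes of translesion synthesis, also adjusted over the list alone. In mismatch repair, 0 of 12 genes passed, also adjusted over the list alone. Among genes that DNA damage switches on, 4 of 30 fell and 1 rose, with 11 changed adjusted over the list alone. CDKN1A, an inhibitor of cyclin-dependent kinases, fell by 2.66 ± 0.20 (adjusted p = 3.32e-05), the stress cytokine GDF15 fell by 2.68 ± 0.42, and the death receptor FAS fell by 1.40 ± 0.23, whereas the ubiquitin ligase MDM2 did not pass at -0.30 ± 0.23 (adjusted p = 0.540). Of 27 proapoptotic genes, 2 rose and 4 fell, with 7 changed adjusted over the list alone, among them BID, which links death receptors to mitochondria, which was at least 3.07-fold lower, and BMF, which was at least 1.49-fold higher. Of 14 antiapoptotic genes, BAG3 rose by 0.94 ± 0.24 and BIRC6 fell by 0.89 ± 0.18, the same number as adjusted over the list alone, while BCL2 and BCL2L1 stood at -0.12 ± 0.19 (adjusted p = 0.802) and 0.09 ± 0.17 (adjusted p = 0.843) without passing. Leaving out 1 array ended the call of ERCC1 (without Pt1 array 2 or 3 or parental array 1, adjusted p up to 0.0654), GTF2H4 (without Pt1 array 1 or 2 or parental array 2 or 3, adjusted p up to 0.0907), EME1 (without any 1 of the Pt1 arrays, OHP array 1 or parental array 1 or 3, adjusted p up to 0.176), BAG3 (without any 1 of the Pt1 arrays, OHP array 1 or any 1 of the parental arrays, adjusted p up to 0.158), and of BIRC6 (without Pt1 array 2 or 3 or parental array 2, adjusted p up to 0.0622). Without OHP array 2, BRCA1 passed at adjusted p = 0.0296.

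Growth and signalling genes moved both ways in Pt1. In the proliferation list, 1 of 38 genes rose and 1 fell, with 0 changed adjusted over the list alone, a median of 0.27 (0.30 with bounds over 36 members) and adjusted p = 0.0146 with the preset correlation (adjusted p = 0.586 with an estimated correlation). The spindle protein TPX2 rose by 1.32 ± 0.33 and the mitotic cyclin CCNB1 fell by 0.64 ± 0.17, the latter with adjusted p = 0.0687 once replicate number was a block. Among 41 receptor tyrosine kinases and ligands, 4 rose and 3 fell, with 8 changed adjusted over the list alone. The ligand NRG1 was at least 4.25-fold higher, the receptor MERTK was at least 2.87-fold higher, and FGFR3 fell by 2.05 ± 0.41. The receptors EGFR and ERBB2 did not pass, at 0.14 ± 0.22 (adjusted p = 0.792) and 0.43 ± 0.32 (adjusted p = 0.509). MAPK pathway output gave 1 gene higher and 3 lower of 20, with 4 changed adjusted over the list alone: the phosphatase DUSP4 was at least 1.75-fold higher, while SPRY2, a feedback inhibitor, fell by 1.84 ± 0.25. Of 11 protein kinase C isoforms, PRKCA fell by 2.10 ± 0.25 (adjusted p = 0.000515), the only change, also adjusted over the list alone. IGF2 was at background in all 3 lines. With 1 array left out, the test was no longer passed by TPX2 (without any 1 of the Pt1 arrays or any 1 of the parental arrays, adjusted p up to 0.133), CCNB1 (without any 1 of the Pt1 arrays or any 1 of the parental arrays, adjusted p up to 0.166) and FGFR3 (without Pt1 array 1 or 2 or parental array 2, adjusted p up to 0.0605). The call of the proliferation list ended without parental array 1, at adjusted p = 0.179.

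Epithelial genes moved both ways in Pt1, with 5 of 34 higher, 6 lower and 11 changed adjusted over the list alone. The keratin KRT18 rose by 2.77 ± 0.74 and the laminin chain LAMB3 rose by 2.41 ± 0.28, while KRT7 fell by 2.36 ± 0.26. CDH1, the adhesion protein of epithelial junctions, was at least 2.16-fold lower (adjusted p = 0.00204). Of 37 mesenchymal genes, 5 rose and 3 fell, with 9 changed adjusted over the list alone. CALD1, which binds actin, rose by 2.44 ± 0.24, and the collagen COL6A1 fell by 2.49 ± 0.47. The filament protein VIM did not pass at 0.16 ± 0.60 (adjusted p = 0.933). With the signal shift index as a covariate, VIM turned to -0.64 and passed (adjusted p = 0.0252). Among 30 integrins and laminins, 3 rose and 4 fell, with 10 changed adjusted over the list alone: ITGB3, a receptor for vitronectin, rose by 2.87 ± 0.41, and ITGB2, a leucocyte integrin, fell by 3.66 ± 0.26. Of 12 endothelial and mesothelial markers, 3 rose, also adjusted over the list alone, with a median of 0.44 (0.65 with bounds over 7 members) and adjusted p = 0.00808 with the preset correlation (adjusted p = 0.137 with an estimated correlation). With only genes above the ceiling in all 9 arrays the call of that list ended, at adjusted p = 0.235. The mesothelial gene LRRN4 was at least 5.54-fold higher and ENG, a TGF-beta coreceptor, was at least 2.95-fold higher. CORO1A was the only 1 of 15 leucocyte markers to pass the test, also adjusted over the list alone, and it rose. CD68, named after its value was seen, did not pass at -1.82 (adjusted p = 0.104). Its log2 values were 9.82 to 9.96 on the Pt1 arrays and 11.66 to 11.75 on the parental arrays. The pooled spread also holds its OHP arrays, at 10.09, 12.5 and 9.49 on arrays 1, 2 and 3. Of 14 fibroblast markers, THY1 fell by 1.22 ± 0.25 and FBLN2 rose, the same number as adjusted over the list alone. The call ended, with 1 array left out, for KRT18 (without any 1 of the Pt1 arrays, OHP array 1 or any 1 of the parental arrays, adjusted p up to 0.164), THY1 (without Pt1 array 1 or 2 or parental array 2, adjusted p up to 0.0648) and FBLN2 (without Pt1 array 2 or 3 or parental array 2, adjusted p up to 0.0565).

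Some cholesterol genes fell in Pt1, and other metabolic, stress and marker genes moved both ways. Of 21 cholesterol genes, 0 rose and 4 fell, with 5 changed adjusted over the list alone, a median of -0.50 (-0.55 with bounds over 20 members) and adjusted p = 0.00781 with the preset correlation (adjusted p = 0.643 with an estimated correlation). CYP51A1, a sterol demethylase, fell by 1.43 ± 0.25, LSS fell by 1.15 ± 0.24, and DHCR7 fell by 0.94 ± 0.26, the last with adjusted p = 0.0678 once replicate number was a block. Of 24 aldehyde dehydrogenases and stem cell markers, 5 rose and 6 fell, with 14 changed adjusted over the list alone. ALDH2, which detoxifies acetaldehyde, rose by 4.51 ± 0.29, and ALDH1A3 was at least 4.2-fold higher, whereas ALDH1A2 was at least 2.27-fold lower. In hypoxia and glycolysis, 3 of 31 genes rose and 1 fell, with 4 changed adjusted over the list alone, among them the peptide hormone ADM, which rose by 3.09 ± 0.20, and the carbonic anhydrase CA12, which was at least 16-fold lower. Of 21 heat shock genes, 4 rose and 1 fell, with 6 changed adjusted over the list alone: HSPH1 rose by 1.40 ± 0.22 and CRYAB was at least 2.16-fold lower. This list was called only without parental array 2 when 1 array was left out, at adjusted p = 0.0452 with the preset correlation. The chaperone PDIA4 fell by 0.81 ± 0.17, alone among 29 genes of unfolded protein and amino acid stress, also adjusted over the list alone. Without parental array 3 that list was called, with a median of -0.54 and adjusted p = 0.0186 with the preset correlation. Of 17 ovarian carcinoma markers, MSLN rose and the folate receptor FOLR1 fell by 3.15 ± 0.25, also adjusted over the list alone. In the cancer-testis list, 2 of 19 genes rose and 2 fell, with 5 changed adjusted over the list alone, among them CTAG2, which was at least 1.88-fold lower. In all 5 lists called with the preset correlation the median, the mean and the test had 1 sign, and in 6 of the 30 lists they parted. Leaving out 1 array ended the call of DHCR7 (without any 1 of the Pt1 arrays, OHP array 1 or 3 or parental array 2 or 3, adjusted p up to 0.192), LSS (without Pt1 array 2 or 3 or parental array 2 or 3, adjusted p up to 0.0718), and of PDIA4 (without any 1 of the Pt1 arrays or parental array 2, adjusted p up to 0.0751).

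The comparison of OHP with parental cells asked which genes differ between cells labelled oxaliplatin-resistant and sensitive cells. The chemokines CXCL8 and CCL20, the cancer-testis antigen MAGEA10, AXL and MSLN were higher in OHP. CDKN1A and 5 other genes that DNA damage switches on were lower, together with EPCAM, CLDN7 and the matrix protein SPON1. Of 18852 genes, 1020 (5.41%) differed, 329 higher and 691 lower in OHP, of which 242 and 467 changed at least 2-fold. The count was 3148 without OHP array 2, and 628, 613 and 590 without parental arrays 1, 2 and 3. Same-numbered OHP and parental arrays deviated from their group means alike, with correlations across genes of 0.126, 0.671 and 0.502, and with replicate number as a block 1021 genes differed over 9 arrays and 796 over the 6 arrays of both lines.

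QPRT, MSLN and MAGEA10 were among the genes that rose furthest in OHP. QPRT was at least 62.5-fold higher and MSLN rose by 5.76 ± 0.28. The cancer-testis genes MAGEA10 and CT55 were at least 37.4-fold and 15.4-fold higher. CES1, a carboxylesterase that activates and inactivates drugs, rose by 4.97 ± 0.26. CPED1, a protein of the secretory pathway, was at least 16.1-fold higher. PTPRR, a phosphatase of MAP kinases, was at least 11-fold higher, and APBB1IP, which activates integrins, rose by 4.25 ± 0.15. CCL20, which draws dendritic cells and lymphocytes, rose by 4.64 ± 0.35. The zinc finger protein ZNF462 was at least 7.62-fold higher, the adhesion receptor ADGRB3 was at least 6.45-fold higher, and AXL was at least 10.9-fold higher. Adjusted p over these 12 genes ran from 1.01e-07 to 0.000370.

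SPON1, KRT24 and CDH17 were among the genes that fell furthest in OHP. SPON1, a spondin of the extracellular matrix, was at least 68.9-fold lower, and RELN, reelin, a matrix glycoprotein, fell by 5.02 ± 0.35. KRT24 fell by 6.52 ± 0.27 and the lymphocyte receptor gene TNFRSF14 fell by 6.23 ± 0.28. ANKRD22 was at least 38-fold lower and AKAP19 was at least 26.4-fold lower. APOM, an apolipoprotein, fell by 5.45 ± 0.24, and C8G, a complement subunit, fell by 5.27 ± 0.41. CDH17, an intestinal cadherin, fell by 5.37 ± 0.30. HBA2, LBP and HLA-DMB fell by 5.44 ± 0.20, 5.22 ± 0.26 and 5.12 ± 0.32. Adjusted p over these 12 genes ran from 4.27e-07 to 5.72e-05.

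**Figure D3:**
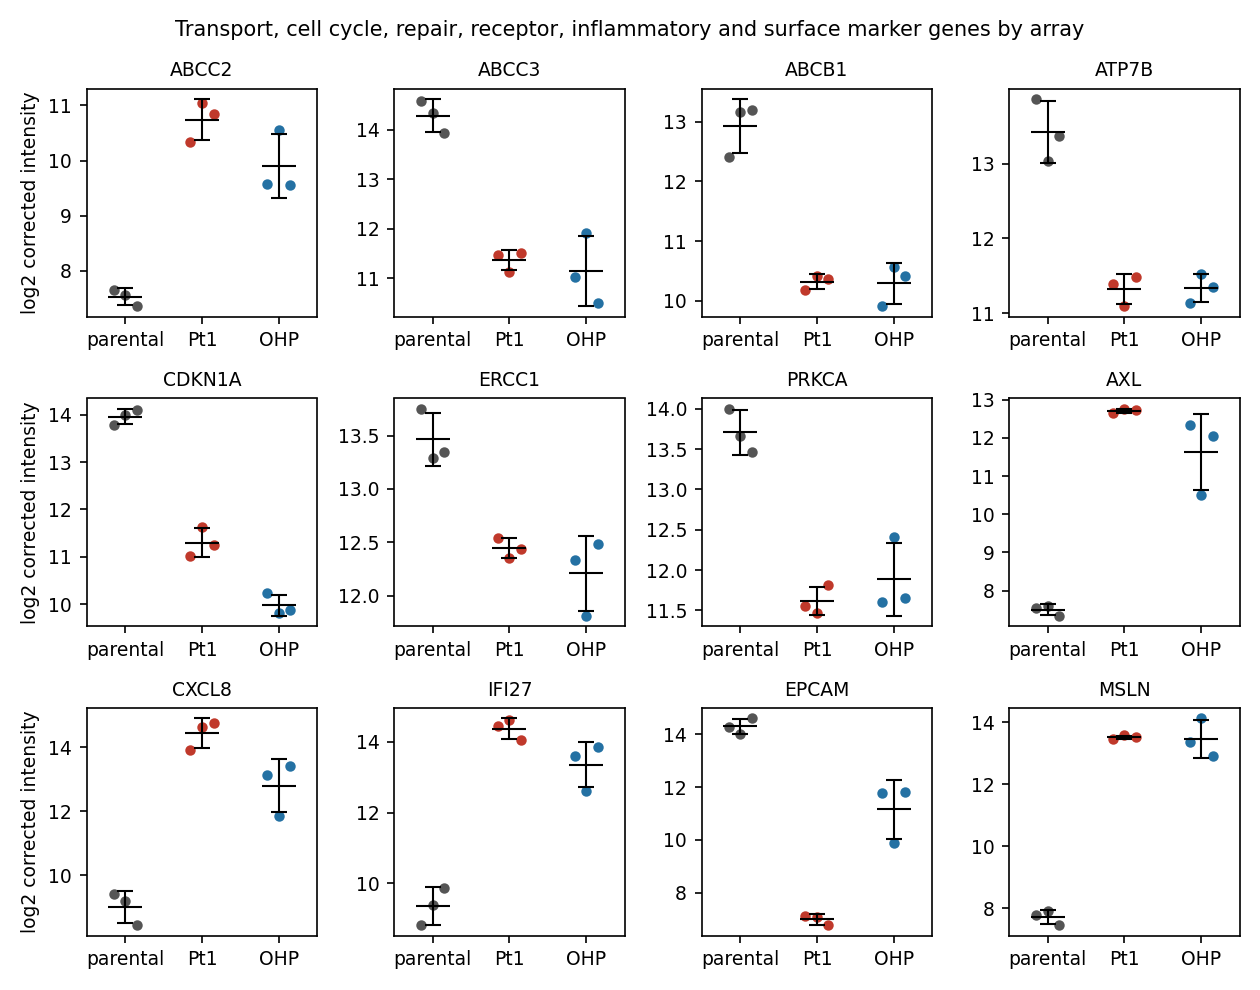
Background-corrected log2 intensity of 12 genes on each of the 9 arrays, by line, with 1 point per array and the mean and SD of 3 arrays in black. Against parental cells, CDKN1A fell by 2.66 in Pt1 on the log2 scale and fell further in OHP.

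Interferon-stimulated genes were split in OHP: 9 of 37 rose, 2 fell and 26 did not pass, with 16 changed adjusted over the list alone. Their median was 0.58 (0.60 with bounds over 33 members) and was 0.33 without OHP array 2, with adjusted p = 6.16e-08 with the preset correlation and adjusted p = 0.210 with an estimated correlation. IFI27 rose by 3.99 ± 0.36, IFI44 rose by 2.38 ± 0.37 and OAS2 was at least 2.23-fold higher. The 2 that fell were the ubiquitin ligases HERC6 and HERC5, at least 1.48-fold and 1.86-fold lower. Of 31 NF-kB targets and cytokines, 7 rose and 0 fell, with 9 changed adjusted over the list alone, a median of 0.29 (0.53 with bounds over 23 members) and adjusted p = 1.69e-06 with the preset correlation (adjusted p = 0.210 with an estimated correlation). CXCL8 rose by 3.79 ± 0.42, CCL2 was at least 2.61-fold higher and IL32 rose by 2.45 ± 0.22. Antigen presentation had 1 of 21 genes higher and 1 lower, with 3 changed adjusted over the list alone, a median of 0.40 (0.55 with bounds over 18 members) and adjusted p = 0.0377 with the preset correlation. That p was 0.108, 0.123 and 0.155, and the median 0.23, 0.21 and 0.24, without OHP array 1, OHP array 3 and parental array 2, and adjusted p = 0.421 with an estimated correlation. The class II gene HLA-DPA1 rose and HLA-DMB fell. With 1 array left out, the test was no longer passed by OAS2 (without parental array 2, adjusted p = 0.0549) and HLA-DPA1 (without any 1 of the Pt1 arrays, OHP array 1 or 3 or any 1 of the parental arrays, adjusted p up to 0.162).

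Genes that DNA damage switches on mostly fell in OHP where they passed, with 6 of 30 lower, 1 higher and 10 changed adjusted over the list alone. The list had a median of -0.18, also with bounds over 26 members, and adjusted p = 0.0377 with the preset correlation (adjusted p = 0.210 with an estimated correlation). Without OHP array 2 the list gave adjusted p = 0.239, and without parental array 2 adjusted p = 0.0599. With array weights it gave 0.183, and with the signal shift index as a covariate 0.0779. With only genes above the ceiling in all arrays of a line it gave 0.0739, and in all 9 arrays 0.406. CDKN1A fell by 3.98 ± 0.20 (adjusted p = 3.54e-06), FAS fell by 2.41 ± 0.23, and MDM2 fell by 1.01 ± 0.23 (adjusted p = 0.0360), the last with adjusted p = 0.0588 in a block of the 6 arrays of both lines. Of 27 proapoptotic genes, 0 rose and 2 fell, FAS and BAX, a pore former of mitochondria, which fell by 1.32 ± 0.25, also adjusted over the list alone. BCL2, which blocks that pore, fell by 0.91 ± 0.19 (adjusted p = 0.0232), the only change among 14 antiapoptotic genes, also adjusted over the list alone, with adjusted p = 0.0569 in the block of 6 arrays. BCL2L1 did not pass at -0.34 ± 0.17 (adjusted p = 0.399). In nucleotide excision repair ERCC1 fell by 1.25 ± 0.21 (adjusted p = 0.00726) and RPA1, which binds single-stranded DNA, fell by 0.84 ± 0.20, the 2 changes of 27 genes, also adjusted over the list alone. RPA1 had adjusted p = 0.0710 with the block. In homologous recombination and Fanconi anaemia 0 of 33 genes passed, in mismatch repair 0 of 12 and in translesion synthesis 0 of 15, each also adjusted over the list alone. BRCA1 stood at 0.24 ± 0.18 (adjusted p = 0.627). The call ended, with 1 array left out, for MDM2 (without any 1 of the Pt1 arrays, OHP array 1 or any 1 of the parental arrays, adjusted p up to 0.131), BAX (without OHP array 1 or parental array 1 or 3, adjusted p up to 0.0615), BCL2 (without OHP array 1 or 3 or any 1 of the parental arrays, adjusted p up to 0.103) and RPA1 (without any 1 of the Pt1 arrays, OHP array 1 or 3 or parental array 2 or 3, adjusted p up to 0.162).

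Platinum transporters moved both ways in OHP as well, with 1 of 19 higher, 5 lower and 9 changed adjusted over the list alone. ABCC2 was at least 3.48-fold higher (adjusted p = 0.00119), ABCC3 fell by 3.14 ± 0.33 (adjusted p = 0.000443), ABCB1 fell by 2.62 ± 0.25 (adjusted p = 0.000252) and ATP7B fell by 2.09 ± 0.23 (adjusted p = 0.000568). SLC47A1, which extrudes organic cations, was at least 7.31-fold lower. SLC31A1 and ATP7A did not pass, at -0.23 ± 0.65 (adjusted p = 0.927) and -0.08 ± 0.21 (adjusted p = 0.920). MT2A, the only metallothionein of 9 to pass, rose by 1.41 ± 0.25, with 2 changed adjusted over the list alone. Only 3 of the 9 lay above background in either line. In the glutathione and NRF2 list 1 of 38 genes rose and 4 fell, with 5 changed adjusted over the list alone: AKR1C3 rose by 2.71 ± 0.20 and the quinone reductase NQO1 fell by 1.57 ± 0.23. GSTP1 stood at -0.01 ± 0.13 (adjusted p = 0.990) without passing. Leaving out 1 array ended the call of MT2A (without parental array 3, adjusted p = 0.0536).

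Of 34 epithelial markers, 6 fell and 1 rose in OHP, with 8 changed adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.102 with the preset correlation). It was called without OHP array 1 and without OHP array 3, at adjusted p = 0.0366 and 0.0333 with that correlation. CLDN7, a claudin of tight junctions, was at least 9.86-fold lower, EPCAM fell by 3.14 ± 0.46, and the keratin KRT19 fell by 1.98 ± 0.20, while CDH1 did not pass at -0.97 ± 0.28 (adjusted p = 0.0852). Of 37 mesenchymal genes, 4 rose and 1 fell, with 7 changed adjusted over the list alone: the collagen COL5A1 rose by 1.41 ± 0.24 and the smooth muscle actin ACTA2 fell by 1.64 ± 0.15. VIM stood at -0.59 ± 0.60 (adjusted p = 0.755) without passing. Among 30 integrins and laminins, 0 rose and 5 fell, with 6 changed adjusted over the list alone, among them the collagen receptor ITGA2, which fell by 3.10 ± 0.32. Receptor tyrosine kinases and ligands gave 4 genes higher and 4 lower of 41, with 10 changed adjusted over the list alone. GAS6, the ligand of AXL, rose by 2.67 ± 0.36, the collagen-sensing kinase DDR2 rose by 1.88 ± 0.22, and the growth factor PDGFB fell by 2.10 ± 0.24. EGFR and ERBB2 did not pass, at 0.29 ± 0.22 (adjusted p = 0.629) and 0.47 ± 0.32 (adjusted p = 0.580). In MAPK pathway output 0 of 20 genes rose and 3 fell, with 4 changed adjusted over the list alone, SPRY2 by 1.44 ± 0.25 and DUSP5 by 1.12 ± 0.18. Of 11 protein kinase C isoforms, PRKCA fell by 1.82 ± 0.25 (adjusted p = 0.00202) and PRKCI fell by 0.90 ± 0.21, also adjusted over the list alone, the latter with adjusted p = 0.0689 with the block. With 1 array left out, the test was no longer passed by PRKCI (without any 1 of the Pt1 arrays, OHP array 1 or 3 or parental array 2 or 3, adjusted p up to 0.135). Without OHP array 2, CDH1 passed at adjusted p = 0.00102.

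Metabolic and marker genes changed by few members in OHP. Of 21 cholesterol genes, 0 rose and 1 fell, SC5D by 0.84 ± 0.19, with adjusted p = 0.0582 with the block, and 4 changed adjusted over the list alone. Their median was -0.43 (-0.44 with bounds over 20 members), with adjusted p = 0.0377 with the preset correlation and adjusted p = 0.646 with an estimated correlation. Without OHP arrays 1, 2 or 3 the list gave adjusted p = 0.0547, 0.103 and 0.103, and without parental arrays 2 and 3 it gave 0.155 and 0.136. The median was -0.66, -0.24 and -0.26 without parental arrays 1, 2 and 3. In hypoxia and glycolysis 0 of 31 genes rose and 3 fell, with 6 changed adjusted over the list alone, among them CA12, which fell by 4.59 ± 0.19, and the neuronal enolase ENO2, which fell by 4.15 ± 0.30. Of 24 aldehyde dehydrogenases and stem cell markers, 0 rose and 4 fell, with 9 changed adjusted over the list alone, including the filament protein NES, which was at least 5.65-fold lower, and the transcription factor SOX9, which fell by 2.24 ± 0.43. Of 21 heat shock genes 3 rose, also adjusted over the list alone, among them CRYAB, which rose by 3.02 ± 0.29. The heat shock list was not called (adjusted p = 0.208 with the preset correlation). Without OHP array 2 it was called, at adjusted p = 0.00657 with that correlation. In the cancer-testis list 3 of 19 genes rose and 2 fell, with 5 changed adjusted over the list alone: SSX1 rose by 1.97 ± 0.31 and MAGEC2 rose by 1.71 ± 0.27, while CTAG2 was at least 1.88-fold lower. Of 17 ovarian carcinoma markers, MSLN rose and FOLR1 fell by 2.36 ± 0.25, also adjusted over the list alone. In the proliferation list CDC25C rose by 0.68 ± 0.15, with adjusted p = 0.0636 with the block, and the mitotic kinase AURKB fell by 1.04 ± 0.18, the 2 changes of 38 genes, also adjusted over the list alone. None passed among 29 genes of unfolded protein and amino acid stress, 15 leucocyte markers and 14 fibroblast markers, each with 0 changed adjusted over the list alone, or among 12 endothelial and mesothelial markers, with 2 changed adjusted over the list alone. In all 5 lists called the median, the mean and the test had 1 sign, and in 5 of the 30 lists they parted. The call ended, with 1 array left out, for SC5D (without Pt1 array 2, OHP array 1 or 3 or any 1 of the parental arrays, adjusted p up to 0.125), SOX9 (without parental array 1, adjusted p = 0.0624) and CDC25C (without any 1 of the Pt1 arrays, OHP array 1 or any 1 of the parental arrays, adjusted p up to 0.112).

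Both resistant lines were then compared for changes in common. MSLN, AXL and the chemokines CXCL8 and CCL2 rose in both lines, and KRT24, TNFRSF14 and CDH17 fell in both. Of the genes tested, 136 were higher and 379 lower in both lines, against 13.7 and 39.6 for lists drawn independently. At least 2-fold in both were 99 of the higher and 258 of the lower genes. Part of the overlap may come from the shared parental arrays, which are too few to be divided between the lines. The higher count was 817 without OHP array 2, 85 without Pt1 array 2, and 89, 90 and 84 without parental arrays 1, 2 and 3. The lower count was 1143 without OHP array 2, and 244, 234 and 237 without parental arrays 1, 2 and 3. Across genes, which are not independent replicates, the changes in both lines correlated at r = 0.461, against 0.50 in 50 simulations of groups without effects measured against the same parental arrays, and their covariance was 0.180 against 0.0381. The actin regulator ARHGDIB was at least 4.83-fold higher in Pt1 and was at least 5.33-fold higher in OHP, and the lipid phosphatase INPP4B rose by 3.09 ± 0.19 and rose by 3.73 ± 0.19. APOM fell by 5.46 ± 0.24 in Pt1 and CDH17 fell by 5.64 ± 0.30, near their falls of -5.45 and -5.37 in OHP.

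**Figure D4:**
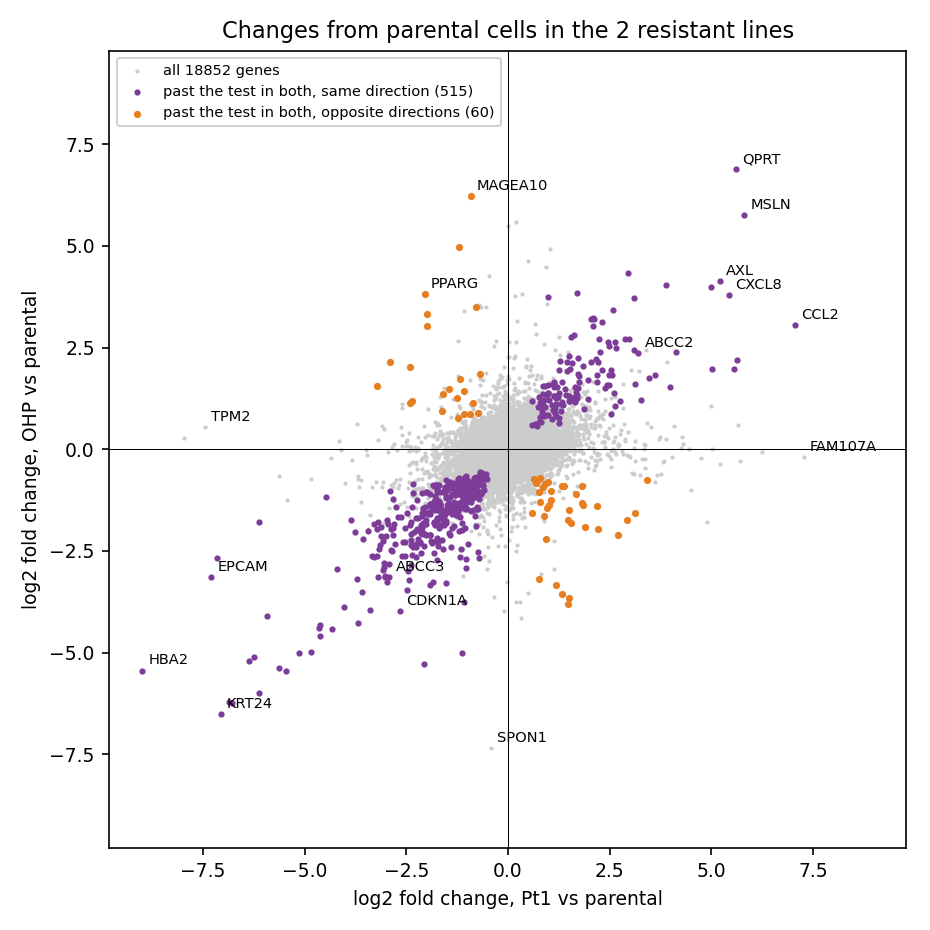
Log2 fold change against parental cells in Pt1 (horizontal) and OHP (vertical), 1 point per gene for 18852 genes, coloured by whether the gene passed the test in both lines. In both lines 136 genes were higher and 379 lower, and 60 went in opposite directions, against 47.5 for lists drawn independently.

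The comparison of OHP with Pt1 asked how the resistant lines differ from each other, which is also the test of the difference between their changes from parental cells. Of 37 interferon-stimulated genes 12 were lower in OHP than in Pt1 and 25 did not pass, cancer-testis antigens differed in both directions, and PPARG, EPCAM and TPM2 were higher in OHP. Of 18852 genes, 1430 (7.59%) differed, 662 higher and 768 lower in OHP, of which 450 and 536 changed at least 2-fold. The count was 2297 without OHP array 2, and 770, 733 and 753 without Pt1 arrays 1, 2 and 3. Among all 3 lines together, 2327 genes (12.3%) differed in limma's moderated F-test. That count was 5544 without OHP array 2, and 1383, 1312 and 1346 without Pt1 arrays 1, 2 and 3.

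Genes that parted the resistant lines furthest included several that were at background in 1 line. PAGE1, TPM2 and MAGEA10 were at least 111-fold, 95.7-fold and 37.4-fold higher in OHP. PPARG, a nuclear receptor of lipid metabolism, was at least 19.7-fold higher, CES1 was at least 38.1-fold higher, and CT55 was at least 15.4-fold higher. Lower in OHP were FAM107A, which was at least 65-fold lower, SPON1, which was at least 51.6-fold lower, and MCUB, which was at least 24.1-fold lower. SGCE, a sarcoglycan, fell by 6.70 ± 0.46, MAL fell by 6.33 ± 0.20, and PTGR1 was at least 15.4-fold lower. Adjusted p over these 12 genes ran from 2.75e-08 to 1.68e-05.

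The interferon list was the only 1 of 30 called between the resistant lines, with 12 of 37 genes lower and 0 higher in OHP and 17 changed adjusted over the list alone. Its median was -0.87 (-0.77 with bounds over 35 members), with adjusted p = 1.58e-07 with the preset correlation and adjusted p = 0.70 with an estimated correlation. HERC6 and HERC5 were at least 3.54-fold and 3.17-fold lower, SAMD9 fell by 1.86 ± 0.28, and IFI44 fell by 1.74 ± 0.37. Of 31 NF-kB targets and cytokines, 2 were higher and 5 lower in OHP, with 7 changed adjusted over the list alone: CCL20 rose by 4.13 ± 0.35, whereas CCL2 fell by 4.01 ± 0.32 and CXCL10 fell by 2.97 ± 0.40. CXCL8 fell by 1.64 ± 0.42, with adjusted p = 0.0599 with the block. CDKN1A fell by 1.32 ± 0.20 (adjusted p = 0.00333), GDF15 rose by 1.80 ± 0.42, and BID was at least 3.23-fold higher. EPCAM was at least 7.93-fold higher and KRT7 rose by 3.56 ± 0.26, while CLDN7 was at least 4.69-fold lower. ALDH2 was at least 20-fold lower, NES was at least 15.1-fold lower, and CRYAB was at least 15.2-fold higher. GAS6 rose by 3.88 ± 0.36 and NRG1 was at least 4.25-fold lower. None of ABCC2, ATP7B, ERCC1, PRKCA, MDM2 and VIM passed between the lines, at -0.84 ± 0.29, 0.02 ± 0.23, -0.23 ± 0.21, 0.27 ± 0.25, -0.72 ± 0.23 and -0.74 ± 0.60 on the log2 scale. ABCC2 passed without OHP array 2, at adjusted p = 0.00186, and MDM2 without OHP array 3, at adjusted p = 0.0166. Leaving out 1 array ended the call of CXCL8 (without any 1 of the Pt1 arrays, OHP array 1 or any 1 of the parental arrays, adjusted p up to 0.180), GDF15 (without any 1 of the Pt1 arrays or OHP array 1 or 3, adjusted p up to 0.131), and of IFI44 (without Pt1 array 1 or 2, adjusted p up to 0.0974).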

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

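The tests of the probe pairs, of the genes that fell furthest in OHP, of leucocyte markers and of splits within numbers, and the fits with the signal shift index, were chosen only after the results were seen.

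The changes from parental cells differed between Pt1 and OHP for 1430 genes, by the test of OHP against Pt1. Of the splits of the 6 arrays of these lines, 1 of 10 gave as many genes, the real split, and the highest other gave 0. For Pt1 against parental the real count was 1863 and the highest other 0 (1 of 10 splits as large), and for OHP against parental 1020 and 1 (1 of 10). The 10 splits of 3 against 3 arrays are too few for a share under 0.05. In OHP and parental, whose same-numbered arrays deviated alike, the 3 other splits that part every pair gave 0. For the 3 lines together, 1 of 100 drawn splits of the 280 possible gave as many as the real 2327 genes, and the highest other drawn gave 570. Of the 36 splits that exchange labels only between arrays with the same number, 1 gave as many and the highest other gave 570. A split outside both sets, with OHP array 2 exchanged for parental array 3, gave 2574 genes, more than the real one. A share under 0.05 of splits with as many genes had been set beforehand against chance. The 100 drawn splits met that bound, and the share among the splits within numbers was 0.0278. As not all 280 splits were run and 1 exceeded the real one, the share over all splits is not known. Chance as the source of the count of 2327 is therefore not fully excluded. Exchanging OHP array 2 for parental array 2 instead gave 570 genes, and what gave the 2574 was not tested.

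Changes in opposite directions were seen for 60 genes, against 47.5 for lists drawn independently, with 37 higher in Pt1 and lower in OHP and 23 the reverse. Examples among the genes named in the comparisons are CRYAB, which was at least 2.16-fold lower in Pt1 and rose by 3.02 ± 0.29 in OHP, KRT7, which fell by 2.36 ± 0.26 and rose by 1.20 ± 0.26, and NES, which rose by 1.48 ± 0.33 and was at least 5.65-fold lower. No explanation was tested for these genes.

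OHP array 2 and parental array 2 lay apart from the other arrays of their lines, on a signal shift index of -4.22 and -1.55. Pairs of probes of 1 gene that drift apart on OHP array 2 had an index of 2.30 on parental array 2, against 1.17 and 1.41 on the other parental arrays. As the pairs were chosen on OHP array 2, with which parental array 2 deviates, unequal loss of signal between probes and any other shared shift cannot be told apart. OHP array 2 correlated with parental array 2 at 0.956, more than with the other OHP arrays, which goes with a mixture and with a shared shift alike. As OHP arrays 1 and 3 correlated with parental array 2 at 0.962 and 0.952, OHP array 2 was not particularly close to it. Mixing with parental RNA was tested by the position of OHP array 2 between parental (0) and OHP (1): 0.521 (95% interval 0.391 to 0.616) over 473 risen and 0.698 (0.649 to 0.747) over 696 fallen genes. A position under 0.7 had been set beforehand for a mixture. Both medians met that bound, although the second interval spans it. Yet 3104 genes were chosen as alike on the other OHP arrays and parental arrays 1 and 3, and on arrays not used to choose them their SD was 1.01 on OHP array 2, 0.39 on parental array 2 and 0.494 to 0.509 on the Pt1 arrays, so genes with small changes are moved by the shift itself. The 54 genes that fell at least 8-fold in the other OHP arrays lay at 1.01 (0.933 to 1.03), a parental share of -0.144% (-0.609 to 0.807), which argues against a mixture and against a swap. This test was chosen after the planned one, which by itself goes with a mixture. The intervals of these positions and of the share come from resampling genes, and do not measure the spread between arrays.

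Of 37 interferon-stimulated genes 24 were higher in Pt1 than in parental cells, and 12 were lower in OHP than in Pt1 by the test of the difference. The signal shift does not account for the rise in Pt1 as its whole cause, since the list's median was 1.45 with the index as a covariate (28 of 37 genes higher) and 1.23 with OHP array 2 also left out (22 higher), against 1.49 (24 higher). Leucocyte markers did not rise along as a set: in deposited intensity, Pt1 minus parental, the interferon-stimulated genes gained a median of 848 units (95% interval 486 to 1290) and 15 leucocyte markers -11.5 (-31.2 to -5.29). The intervals come from resampling genes within a list and do not measure the spread between arrays. Intensities of different probes are not on 1 scale, and only 2 of 15 markers lay above the ceiling in all Pt1 arrays. A small share of leucocyte RNA is thus not excluded. CORO1A gained 173 units and passed the test, and the next highest marker gained 25.2. A difference of the line stays open, and what sets it off was not tested.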

How the results depend on the processing

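All alternatives with the background ceiling, offset 16, the signal shift index, OHP array 2 and parental array 2 left out together, and the block of 6 arrays were chosen only after the data were seen. Counts moved with the arrays and with the estimate of spread. All counts are given as Pt1 against parental, OHP against parental, OHP against Pt1, the 3 lines, higher in both and lower in both.

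With only genes above the ceiling in all 9 arrays the counts were 1071, 496, 757, 1318, 79 and 181, since fewer genes are tested. Array weights gave 4889, 3371, 4587, 6703, 709 and 1121. Leaving out OHP array 2 and parental array 2 together gave 4105, 2508, 2708, 4934, 602 and 895, and the signal shift index as a covariate gave 4101, 3796, 3199, 5739, 724 and 1065. With the covariate and without OHP array 2, OHP against Pt1 gave 3009 and the 3 lines 3520. With only the 6 arrays compared, Pt1 against parental gave 4882, OHP against parental 481, OHP against Pt1 847 and lower in both 236. Testing against a log2 fold change of 0.5 instead of 0, a stricter test, gave 690, 373 and 494, with 53 higher and 138 lower in both. For Pt1 against parental, the OHP arrays enter only the pooled spread. The median over all genes was -0.0204 with all arrays, without OHP array 2 and with only the 6 arrays compared. The counts of 4877 and 4882 in these 2 settings, against 1863, thus come from the estimate of spread. Apart from this, the ceiling and the stricter test, the cause was not tested.

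Leaving out 1 array at a time, the counts ran from 1039 to 4877, 590 to 3148, 733 to 2297, 1312 to 5544, 84 to 817 and 234 to 1143, each highest without OHP array 2. Lists kept their sign: the median of interferon-stimulated genes ran from 1.30 to 1.56 in Pt1 and 0.33 to 0.75 in OHP, and that of NF-kB targets and cytokines from 0.31 to 0.47 and 0.20 to 0.40. Over all alternatives but the estimated correlation these medians ran from 1.23 to 1.58, 0.33 to 0.75, 0.22 to 0.72 and 0.20 to 0.54. With an estimated correlation between genes these 4 calls ended, at adjusted p = 0.0899 (median 1.49) and 0.210 (0.58) for interferon-stimulated genes and 0.137 (0.39) and 0.210 (0.29) for NF-kB targets and cytokines. They passed in all of the other 20 alternatives in Pt1 and 21 in OHP.

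Of 279 named results past the test, 192 passed in every alternative and 246 in at least 15, and all 279 kept 1 sign. The log2 fold change of VIM in Pt1, 0.16, was -0.64 with the covariate and passed there (adjusted p = 0.0252). That of SLC31A1, 0.46, was -0.89 with the covariate and without OHP array 2, and passed there (adjusted p = 0.0400). The cause of these turns was not tested. Genes higher made up 32.3% of the changes in OHP, 44.5% with the covariate and 41.9% without OHP array 2. Without background correction, which coincides with the values as deposited, the counts were 1963, 1128, 1453, 2447, 152 and 418. These counts also stayed within 1.5 times with offset 16, a variance trend, the replicate block, every probe by itself and the ceiling in all arrays of a line. The alternatives that need detection p-values, neqc with offset 50 and the chip as a block were not run. Signal over background limits what can be seen, since 10700 of 18852 genes lay above the ceiling in all arrays of a line.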

Other observations

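The search for runs of neighbouring genes and the genes and runs named here were chosen only after the data were seen, while the tests of the chromosome 17 run against the signal shift and for copy loss were set before their results.

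Neighbouring genes changed together in both resistant lines. There were 7 runs in Pt1 against parental, 10 in OHP against parental and 11 in OHP against Pt1, of windows beyond the shuffled extremes of -0.79 and 0.72, -0.60 and 0.53, and -0.77 and 0.73. The counts depend on the shuffles and on the arrays: another draw of shuffles gave 6, 10 and 7, and with 1 array left out they ran from 5 to 8, 6 to 10 and 6 to 13. In 5 of the 10 OHP runs the median moved by over 1.5 times without 1 OHP array, from -0.60 to -0.33 (without array 3), -0.53 to -0.34 (without array 1), and 0.55 to 0.32, 0.54 to 0.22 and 0.57 to 0.09 (without array 2). In OHP, 149 genes on chromosome 17 from RPH3AL to UBB had a median log2 fold change of -0.79, with 132 below 0. CLDN7, AURKB and RPA1 lie in it, of which CLDN7 was at least 9.86-fold lower, AURKB fell by 1.04 ± 0.18 and RPA1 fell by 0.84 ± 0.20, the last with adjusted p = 0.0710 once replicate number was a block. On chromosome 5, 48 genes from CCDC127 to DNAJC21 had a median of -0.66 in OHP and 0.08 in Pt1. On chromosome 19, 140 genes from PLPP2 to XAB2 had a median of 0.54 in OHP, which was 0.22 without OHP array 2. In Pt1, 114 genes on chromosome 19 from LSR to ZNF574 had a median of -0.84, and -0.61 with the signal shift index as a covariate. In Pt1, 29 genes on chromosome 4 from ABCA11P to SH3BP2 had a median of -0.87, and -0.56 with that covariate.

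The chromosome 17 run in OHP was weighed further. A shared signal shift predicts a like fall in Pt1, whose index lay above the parental one as on OHP arrays 1 and 3, but the same genes had a median of -0.0082 there, and -0.79 in OHP without OHP array 2. The medians of single OHP arrays against the parental mean were -0.79, -0.56 and -0.79, but the genes were chosen for their fall in these arrays and DNA was not analysed here, so a loss of DNA copies and a shared change of regulation cannot be told apart.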
